A study of Gossypium hirsutum with 7 samples.

How the data were processed

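RNA from whole cotton ovules (Gossypium hirsutum, an allotetraploid with A and D copies of most genes) at 0 days post anthesis, the day of flowering when fibre cells start to grow out of the ovule surface, was hybridised to a 1-colour Affymetrix cotton array, 1 sample per array. The labels gave 7 arrays in 3 groups: 2 of wild type, 2 with the homeodomain gene GhHD-1 silenced, and 3 over-expressing it. The sample titles do not say whether a transgenic group is 1 line or several, and each group is called a line below. The labels call the arrays of a group biological replicates and say that ovules to be compared came from plants of the same glasshouse and day.

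The values deposited by the authors were log2 intensities per probe set, between 2.27 and 14.55. Per the submitters' processing notes R 2.7.1, RMA and limma were used. The notes give these names with no role or order, and other steps are not given in the sources used here. RMA corrects background, equalises the distributions of the arrays by quantiles and summarises the probes of each set, so global shifts between groups are removed and low signals are compressed. No further transformation was applied for the main results. The table held 24132 probe sets. The 103 AFFX controls and the 52 RPTR reporter controls were set apart and 23977 probe sets were tested; the plan named only the AFFX controls for removal, and the reporter controls were taken out with them because they are not cotton genes of interest. Of the tested probe sets, 9270 end in _s_at and 1556 in _x_at, marks of sets that can read several related transcripts, so gene copies and family members may be mixed in 1 value.

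Probe sets were named through the platform annotation: 697 had 1 gene, 46 had several and 23234 had none listed. All 697 matched the RefSeq gene table of assembly Gossypium_hirsutum_v2.1, and 324 of them, from 246 genes, had a name beyond a locus number. Those with several genes were not named, and no coordinates are given because the array files name no build. No probe set was annotated as GhHD-1, so the level of the targeted gene is not reported here.

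Differences were tested with limma 3.58.1 in R 4.3.3: lmFit on all 7 arrays with 1 mean per group, contrasts and eBayes with default settings, which left 4 residual and 3.01 prior degrees of freedom. p-values were two-sided and adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Fold changes are log2 differences with moderated standard errors (SE). The number of arrays, 2 or 3 per group, limits the precision. On data simulated from these probe sets with 200 of 23977 changed, 5 runs with a shared spread recovered 51.6%, 56.7% and 58.7% of 2-fold and 85.6%, 88.9% and 89.6% of 4-fold changes for silenced against wild type, over-expression against wild type and over-expression against silenced, with 5.6, 7.4 and 8.6 false calls on average. When each group was given its own measured spread, the false calls were 85.8, 154 and 14.4. The groups did not share a spread, and the data themselves gave 0, 1 and 5 calls. The recoveries may therefore not hold for these arrays.

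Gene groups were tested with camera at a preset inter-gene correlation of 0.01. The lists planned before the data were examined were regular expressions on gene names and products. The annotation held only short symbols, so 4 of these 21 lists reached the minimum of 5 probe sets. They were therefore filled by symbol into 22 lists, after the names were seen but before any group difference was tested. Of these, 17 had at least 5 probe sets, giving 51 tests adjusted together. The lists of fasciclin-like proteins, NAC, MADS and AP2 factors, MAP kinases and terpenoid genes were formed at that stage. Homeobox genes, WRKY factors, gibberellin and brassinosteroid genes, terpenoid and defence genes and histones had fewer and were not tested; no member was annotated for the photosynthesis, pollen and heat shock lists. The fibre, calcium, ethylene, reactive oxygen and WRKY lists name functions known from the published study of these arrays and are not independent evidence. Camera with an estimated correlation, fry and the lists as first written were alternatives.

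The named genes follow a rule set before the data were examined: among called and named probe sets whose arrays did not overlap, the 10 largest changes each way; where fewer than 5 probe sets were called, the 5 highest and 5 lowest moderated t, given as values that did not pass; and up to 3 members with the smallest p of each list. Here the rule was read as covering genes with a name beyond a locus number, the homeobox genes and the lists that were tested. The plan also named GhHD-1 and probe sets called in opposite directions; there were none of either. Unnamed probe sets are given by ID, and these were chosen after their values were seen.

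Alternatives were the replicate number as a block, a fit of only the groups compared, an intensity trend or robust prior in eBayes, a further quantile, median or cyclic loess normalization, leaving out the dimmer probe sets (11989 with a mean of at least 7.64 stayed), array weights, a 2-fold floor, an adjusted p of 0.01 and leaving out each array. Random lists (10000) and the correlation between contrasts that share the wild-type arrays (100 simulations, with a pooled spread and with each group's own) were drawn with fixed seeds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.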

Results

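Expression was measured in ovules at 0 days post anthesis from wild-type cotton (2 arrays), a GhHD-1 silenced line (2 arrays) and a GhHD-1 over-expression line (3 arrays), to ask which genes this homeodomain factor may regulate as fibres initiate. Median log2 intensities of the arrays lay between 7.61 and 7.72, and 5% of the probe sets on each array lay below values of 3.50 to 3.67, so signals near 4 stand close to the floor.

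The silenced arrays resembled each other most, with r = 0.997 across probe sets (probe sets are not independent replicates) and an SD of differences of 0.20 log2 units. The over-expression pairs gave r between 0.985 and 0.995. The wild-type arrays gave r = 0.981, below the correlation of wild-type replicate 1 with silenced replicate 1 (0.987) and of wild-type replicate 2 with over-expression replicate 3 (0.992). The reporter probe set RPTR-Ghi-A06498-1_at separated the silenced line, at 10.07 ± 0.11 (SD, n = 2) against 4.08 to 4.66 on the other arrays. A further reporter probe set, RPTR-Ghi-U57609-2_s_at, read 5.09 on wild-type replicate 1 but 11.88 on the array labelled wild-type replicate 2, above all 5 transgenic arrays (5.91 to 9.84). Every direction against wild type below rests on these 2 arrays as labelled.

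**Figure D1:**
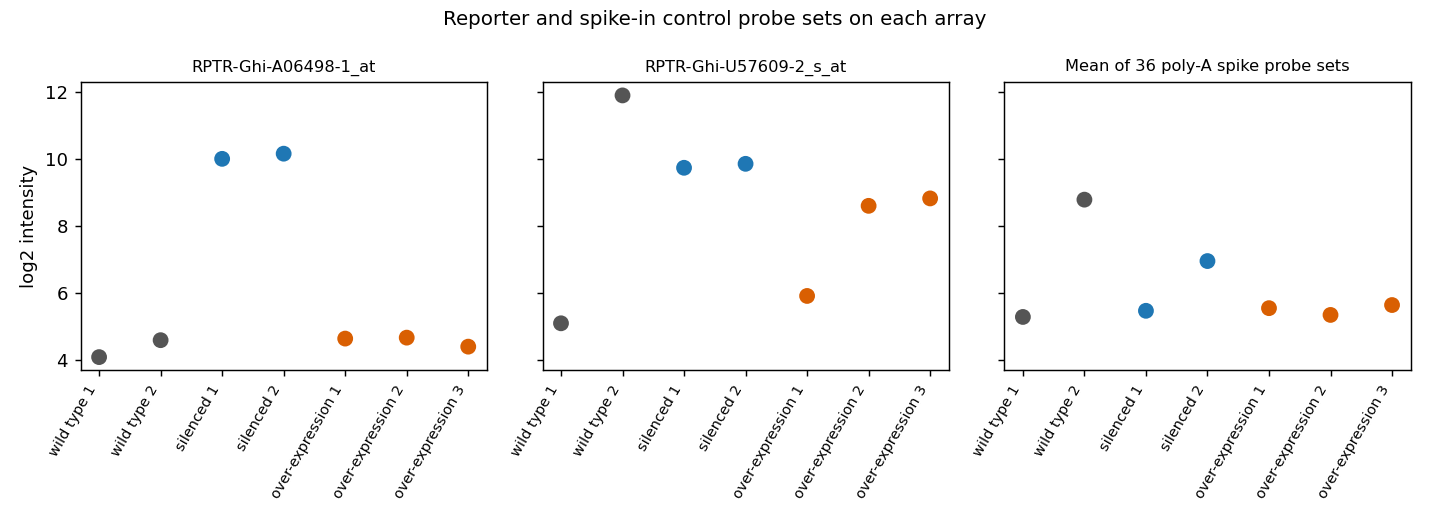
Log2 intensity on each array of the reporter probe sets RPTR-Ghi-A06498-1_at and RPTR-Ghi-U57609-2_s_at and of the mean of 36 poly-A spike probe sets, with colour for the group. The first is near 10 only on the silenced arrays (mean 10.07), and the second is highest on wild-type replicate 2 (11.88).

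**Figure D2:**
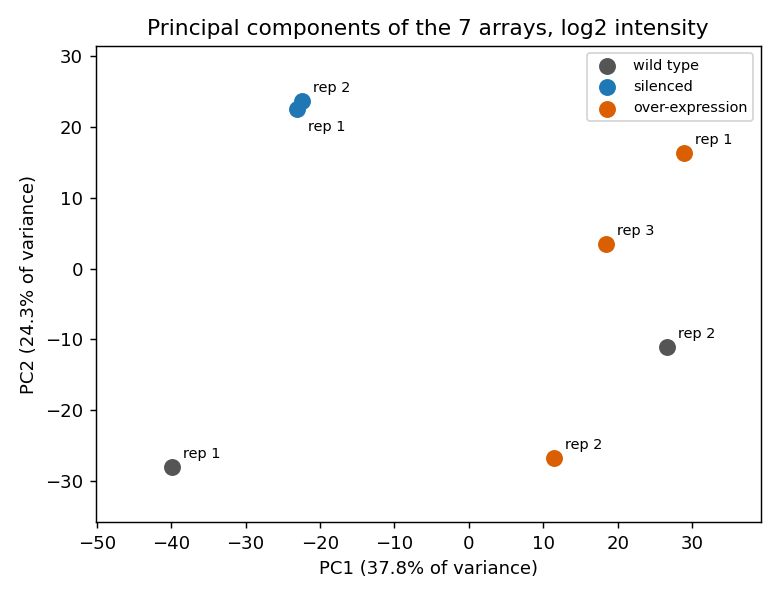
Principal components of the log2 intensities, with 1 point per array and colour for the group. The first component (37.8% of the variance) places wild-type replicate 1 at -39.8 beside the silenced arrays and wild-type replicate 2 at 26.6 among the over-expression arrays.

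In silenced ovules, cell wall genes and an ethylene gene were among the 5 named genes with the lowest moderated t relative to wild type, although no probe set passed the test. The expansin EXPA4, of a family that loosens cell walls, stood at 6.88 ± 0.06 in the silenced line and 7.95 ± 0.03 in wild type (SD, n = 2 each), a log2 difference of -1.07 (SE 0.23, adjusted p = 0.172). The xyloglucan-modifying enzyme gene XTH stood at 8.44 ± 0.01 against 9.43 ± 0.34 (SE of the difference 0.21, adjusted p = 0.158). In over-expression XTH stood at 8.39 ± 0.23 (SD, n = 3), so it was low in both lines. A brighter XTH probe set differed less, with means of 11.83 in the silenced line and 12.18 in wild type. ACO3, an ACC oxidase of the last step of ethylene synthesis, differed by -1.67 (SE 0.36, adjusted p = 0.171). The largest positive moderated t of a named gene belonged to KT, at 9.07 ± 0.08 against 7.95 ± 0.16, a difference of 1.12 (SE 0.17, adjusted p = 0.114). The homeobox gene HB4 differed by the same 1.12 (SE 0.24, adjusted p = 0.172), while HOX3, a homeodomain factor active in fibres, differed by -0.38 (adjusted p = 0.519).

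Limma called 0 of 23977 probe sets between silenced and wild type. The smallest adjusted p was 0.0558, and 3472 probe sets had an unadjusted p under 0.05, where 1199 would be the share of chance. That share takes all groups to vary alike, which they did not, so the excess is not a count of changed genes. The count was 73 without wild-type replicate 1 and 35 without wild-type replicate 2; each leaves a lone wild-type array that is assumed to vary like the other groups. A robust prior gave 7.

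Of the remaining genes of the rule, peroxidase gene pod7 (-0.95, SE 0.20, adjusted p = 0.159) and the gene listed as GRPL1 and rgp1 (-0.91, SE 0.16, adjusted p = 0.135, at a low 3.51 in the silenced line) had values below wild type. The beta-tubulin BTub1 (1.03, SE 0.21, adjusted p = 0.158, also near the floor), the gibberellin receptor GID1-4 (0.68, SE 0.15, adjusted p = 0.175) and the AP2 factor RAV1 (0.72, SE 0.17, adjusted p = 0.185) had values above it. MYB1 differed by 1.45 (SE 0.35, adjusted p = 0.190) and the NAC factor listed as NAC5 and NAC8 by 2.28 (SE 0.76, adjusted p = 0.265). GHTTG1, a WD-repeat protein of the kind that acts in trichome patterning, differed by -0.32 (SE 0.11, adjusted p = 0.277). FatB1, a thioesterase of fatty acid synthesis, differed by -0.81 (SE 0.18, adjusted p = 0.175).

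As a group the 33 cell wall probe sets had a median of -0.20, with 21 below and 12 above wild type, and camera gave an adjusted p of 0.0777 (adjusted p = 0.541 with an estimated correlation). Adjusted over the list alone, 4 of them passed, and 0 over all probe sets. The 10 ethylene probe sets had a median of -0.47 (camera adjusted p = 0.584), of which 2, ACO3 and the response factor ERF3 (-0.79, SE 0.18), passed when adjusted over the list alone; this list and the fibre list are not independent of the study. The 12 fibre probe sets went both ways, with 4 below wild type, among them E6 at -0.62 (SE 0.34) and the expansin EXPA1 at -0.75 (SE 0.42), and 0 passed over the list alone; their median was 0.09, their mean -0.06 and the test pointed down (adjusted p = 0.972). Auxin genes had a median of 0.35 over 7 probe sets (adjusted p = 0.227), led by Aux4 at 1.01 (SE 0.39). Seed storage and late embryogenesis genes, taken as markers of maturing embryo, had a median of 0.19 over 8 (adjusted p = 0.287). Medians of the other tested lists were -0.24 for MAP kinases, -0.34 for phenylpropanoid and flavonoid genes, -0.20 for translation, 0.15 for NAC factors, 0.10 for AP2 factors, 0.07 for lipid and cuticle genes, 0.06 for MYB, bHLH and WD-repeat regulators, 0.05 for MADS factors, 0.04 for fasciclin-like proteins, 0.01 for the cytoskeleton, 0.00 for reactive oxygen genes and -0.0036 for calcium signalling, with adjusted p between 0.378 and 0.965. For the MYB, bHLH and WD-repeat list the test pointed down against a positive median and mean, and for reactive oxygen it pointed down with a mean of -0.06.

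In over-expressing ovules, fasciclin-like arabinogalactan proteins, glycoproteins of the cell surface, were lower as a group than in wild type. Of 19 probe sets from 12 genes, 14 lay below wild type and the median was -0.25 (camera adjusted p = 0.0313, but adjusted p = 0.541 with an estimated correlation). FLA4 stood at 10.21 ± 0.38 (SD, n = 3) against 11.15 ± 0.19 (SD, n = 2), a difference of -0.94 (SE 0.22, adjusted p = 0.407 over all probe sets). FLA14 (-0.40, SE 0.10) and FLA19 (-0.52, SE 0.14) had smaller differences, each with an adjusted p of 0.407. Adjusted over the list alone these 3 passed. In the silenced line FLA14 lay below wild type as well, by -0.32 (SE 0.11). FLA4 and FLA19 lay above it there, by 0.64 and 0.38, with no probe set called. The list's call ended without either wild-type array (adjusted p = 0.0911 without replicate 1 and 0.285 without replicate 2), without over-expression replicate 3 (0.0808) and with 1 probe set per gene (0.442).

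A single probe set without a name, GraAffx.16508.1.A1_x_at, rose in over-expression ovules, from 5.86 ± 0.11 (SD, n = 2) in wild type to 8.09 ± 0.16 (SD, n = 3), 4.69-fold (log2 difference 2.23, SE 0.15, adjusted p = 0.0397). It stood at 7.65 ± 0.24 in the silenced line as well, 1.80 above wild type (adjusted p = 0.0558). Limma thus called 1 of 23977 probe sets, with 2505 at an unadjusted p under 0.05. The fit of only these groups, cyclic loess, the brighter probe sets alone and array weights each called 0. Leaving out either wild-type array leaves a lone one, which is assumed to vary like the other groups. Without wild-type replicate 2 the count was 475 (168 higher, 307 lower), and without wild-type replicate 1 it was 0.

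No named gene passed in this comparison. Values below wild type were led by XTH (-1.04, SE 0.19, adjusted p = 0.393) and the NAC factor NAC2 (-1.29, SE 0.28, adjusted p = 0.407), whose other probe set gave -1.35. A brighter XTH probe set gave a smaller -0.51 (SE 0.21). Values above wild type were led by the ethylene response factor ERF7 (1.08, SE 0.22, adjusted p = 0.397), KCS38, a ketoacyl-CoA synthase of very-long-chain fatty acid elongation (0.72, SE 0.15, adjusted p = 0.407), CPR2 (0.59, SE 0.13, adjusted p = 0.407) and the bHLH factor bHLH110D (0.74, SE 0.18, adjusted p = 0.407). A brighter KCS38 probe set gave a smaller 0.30 (SE 0.14). BTub1 differed by 0.55 (SE 0.20, adjusted p = 0.452). Against wild-type replicate 1 alone, XTH differed by -1.28 and NAC2 by -1.73. Of genes chosen after their values were seen, Aux2 differed by 1.11, HrBP1 by -1.015, GHPDI12 by -1.04, GST by 0.94 and bnlghi6313 by 0.87. A lone array cannot show the spread of wild type. HrBP1, for example, read 11.03 on wild-type replicate 1 and 9.98 on replicate 2, beside 9.95 to 10.13 in over-expression.

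The other lists did not pass in over-expression against wild type, with camera adjusted p between 0.354 and 0.972. Auxin genes had a median of 0.36, seed storage and late embryogenesis genes 0.16, NAC factors 0.14 (mean -0.06), fibre genes 0.13, AP2 factors 0.08, MADS factors 0.07, cytoskeleton genes 0.06, MYB, bHLH and WD-repeat regulators 0.02, translation genes 0.02 and reactive oxygen genes 0.01. Medians lay at -0.02 for MAP kinases, -0.02 for lipid and cuticle genes (mean 0.03), -0.04 for phenylpropanoid and flavonoid genes (mean 0.02), -0.05 for the cell wall, -0.11 for calcium signalling and -0.14 for ethylene (mean 0.07). The fibre, calcium, reactive oxygen and ethylene lists are not independent of the study. Adjusted over the list alone, NAC2 passed at 2 probe sets, and ERF7, bHLH110D, KCS38 and XTH passed at 1 each in their lists.

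**Figure D3:**
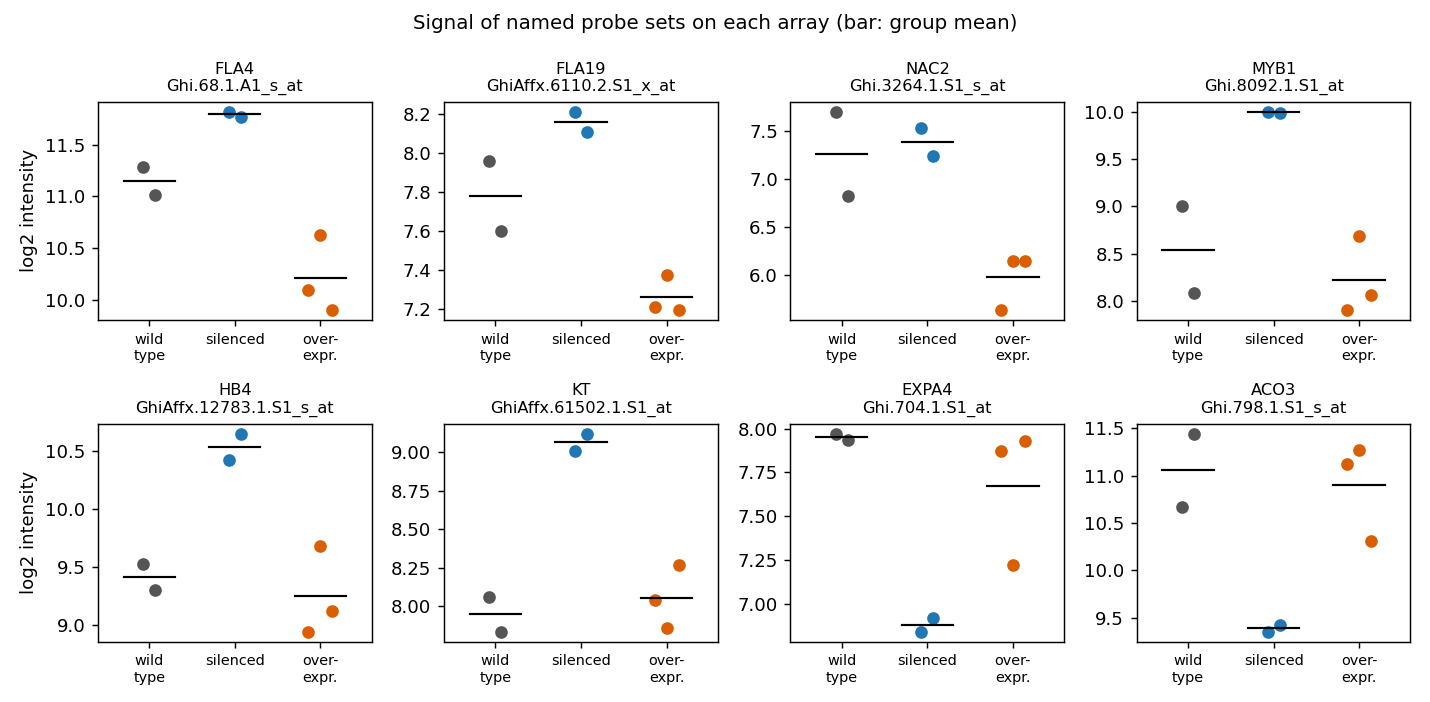
Log2 intensity of 8 named probe sets on each array, with points for arrays and bars for group means; each panel has its own axis, which does not start at 0. FLA4 has means of 11.15, 11.79 and 10.21 in wild type, silenced and over-expression, and EXPA4 has 7.95, 6.88 and 7.67.

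Between the transgenic lines, 4 probe sets were higher in over-expression than in silenced ovules and 1 was lower, none of which has a name in the annotation used. GhiAffx.49524.1.S1_at rose from 6.16 ± 0.19 (SD, n = 2) to 8.50 ± 0.19 (SD, n = 3), 5.05-fold (log2 difference 2.33, SE 0.17, adjusted p = 0.0187). GraAffx.6382.1.S1_at (1.86, SE 0.15, adjusted p = 0.0284), GhiAffx.6053.1.S1_s_at (1.77, SE 0.13, adjusted p = 0.0187) and GhiAffx.1470.1.A1_s_at (1.57, SE 0.10, adjusted p = 0.0187) rose too, and GhiAffx.41780.1.S1_at fell by 1.63 (SE 0.14, adjusted p = 0.0405). In each of the 5 the wild-type mean lay nearer to the over-expression mean than to the silenced mean. At an unadjusted p under 0.05 there were 2892 probe sets. The count of 5 was 1209 (662 higher, 547 lower) with array weights, 9 with median centring, 3 over the brighter probe sets alone and 0 at an adjusted p of 0.01.

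When limma was fitted to the 5 transgenic arrays alone, 238 probe sets passed, 112 higher and 126 lower in over-expression, including those 5, and 153 of them differed by at least 2-fold. The 6 with names were all lower in over-expression: MYB1 (-1.78, SE 0.24, adjusted p = 0.0457), FLA4 (-1.58, SE 0.22, adjusted p = 0.0488), NAC2 (-1.41, SE 0.20, adjusted p = 0.0488), KT (-1.01, SE 0.14, adjusted p = 0.0492), SKD1 (-0.97, SE 0.12, adjusted p = 0.0407, at a low 3.80 in over-expression and named after its values were seen) and FLA19 (-0.90, SE 0.10, adjusted p = 0.0371). In the fit of all 7 arrays FLA4 had an adjusted p of 0.0891 and MYB1 of 0.135. In the fit of all 7 arrays, leaving out either silenced array, or over-expression replicate 1 or 3, gave 0 calls, and leaving out over-expression replicate 2 gave 37.

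Expansins had the smallest p of the cell wall list between the lines, with EXPA3D at 9.74 ± 0.51 in over-expression (SD, n = 3) and 8.18 ± 0.14 in silenced ovules (SD, n = 2), a difference of 1.56 (SE 0.38, adjusted p = 0.197), and a further EXPA4 probe set at a difference of 1.10 (SE 0.23, adjusted p = 0.160). Of 33 cell wall probe sets 21 were higher in over-expression and 5 passed when adjusted over the list alone (median 0.11, camera adjusted p = 0.227). Of 19 fasciclin-like probe sets 14 were lower and 4 passed over the list alone (median -0.08, camera adjusted p = 0.0741). Ethylene genes had a median of 0.56 (adjusted p = 0.287), and ACO3 (1.51, SE 0.33), ERF3 (0.69, SE 0.16) and ERF8 (-0.76, SE 0.18) were among 4 that passed over that list alone. HB4 (-1.29, SE 0.22, adjusted p = 0.133) and HOX3 (0.68, SE 0.23, adjusted p = 0.314) made up the homeobox list, and both passed over it alone. The fibre list had a median of 0.14 (adjusted p = 0.653), with EXPA1 at 0.94 (SE 0.38) and 0 passing over the list alone. All 8 translation probe sets, a broadly expressed control list, were higher in over-expression, with a median of 0.18 (adjusted p = 0.227).

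The remaining lists had camera adjusted p between 0.378 and 0.965 in this comparison. Medians were 0.28 for MYB, bHLH and WD-repeat regulators (mean -0.10), 0.25 for phenylpropanoid and flavonoid genes, with DFR of anthocyanin synthesis at 0.51 (SE 0.14), 0.22 for MAP kinases, 0.05 for reactive oxygen genes, with the peroxidase POX5 at 0.96 (SE 0.23), 0.02 for NAC factors (mean -0.32), 0.02 for the cytoskeleton (mean -0.01), 0.01 for auxin (mean -0.15), -0.03 for seed storage, -0.03 for lipid and cuticle genes (mean 0.00), -0.04 for calcium signalling, -0.05 for MADS factors and -0.17 for AP2 factors. The lists too small to test had medians for silenced against wild type, over-expression against wild type and over-expression against silenced of -0.34, 0.21 and 0.60 for WRKY factors (2 passed over the list alone in the last, and the list is not independent of the study), -0.23, 0.14 and 0.16 for gibberellin and brassinosteroid genes, -0.06, -0.06 and -0.03 for terpenoid and defence genes and 0.00, -0.02 and -0.03 for histones.

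Whether single genes responded in the same or in opposite directions in the silenced and the over-expression line could not be read from the calls, since 0 probe sets were called between silenced and wild type. Across probe sets the log2 fold changes of the 2 lines against wild type had a covariance of 0.0455, with r = 0.452 and the same sign in 71.5% of probe sets. Unchanged groups sharing the same wild-type arrays gave 0.0342, 0.548 and 68.4% in simulation with a spread pooled over the groups, and 0.0605, 0.793 and 72.6% with each group's own spread, chosen after the results were seen. The covariance thus lay above the first and below the second. The shared part comes from the wild-type arrays, which vary most and whose spread the pooled setting understates. The second is therefore the nearer comparison, although it rests on the spread of 2 arrays. No shared response beyond the shared arrays is claimed. Probe sets are not independent replicates, and the wild-type pair is too small to split.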

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

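All tests in this part were chosen after the results were seen, except the cyclic loess test.

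Signals outside the cotton genes stood out in the control probe sets. RPTR-Ghi-A06498-1_at was 5.73 log2 units higher in the silenced line than in wild type, on both silenced arrays. RPTR-Ghi-U57609-2_s_at was 4.64 higher on the lower silenced array than on wild-type replicate 1, and 6.79 higher on wild-type replicate 2 than on replicate 1. The mean of 36 poly-A spike probe sets was 3.50 higher on wild-type replicate 2 than on replicate 1 and 1.48 higher on silenced replicate 2 than on silenced replicate 1. The other 50 reporter probe sets varied by at most 1.46 over the 7 arrays. At most of them wild-type replicate 1 read lowest. The widest of them read 6.37 there and 7.18 to 7.83 on the other arrays. The value below which 5% of the tested probe sets lay was also lowest on that array, at 3.50 against 3.58 to 3.67. A difference in background on that array was not tested as a cause of its distance from the others. The sources used here do not say which sequences the reporter probe sets read.

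The reporter signal on wild-type replicate 2 was weighed first, as a transgene signal there would touch every comparison with wild type. If the probe set read the spikes, wild-type replicate 1 would stand at 8.39, which is 3.30 above its measured 5.09 and far beyond the SD of 0.36 of the spike difference. RNA from a silenced plant would bring the reporter found in that line, which on wild-type replicate 2 lay at -0.0755 relative to the highest over-expression array. RNA from an over-expression plant remains open: at the 238 probe sets called between the transgenic lines without wild-type arrays, wild-type replicate 2 had a median position of 1.04 on a scale from silenced (0) to over-expression (1), and replicate 1 had 0.32. A true wild type would also lie near 1 at probe sets changed only in the silenced line, so this position cannot decide. The called probe set GraAffx.16508.1.A1_x_at read 5.93 on wild-type replicate 2, 5.78 on replicate 1 and 7.9 to 8.19 on the over-expression arrays. It was called on low values of both wild-type arrays, so it cannot decide either. The reporter level of wild-type replicate 2 was 3.07 above the highest over-expression array (the 3 read 5.91, 8.59 and 8.81), so a mislabelled sample cannot be told apart from 2 wild-type samples that differ in state.

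Deviations of wild-type replicate 1 from replicate 2 and of over-expression replicate 2 from the other over-expression arrays had r = 0.217 across probe sets; the values for over-expression replicates 1 and 3 were -0.305 and 0.038, and are not independent of it, as the 3 deviations sum to 0. More degraded RNA on these arrays is argued against by the mean 3′ minus 5′ difference of actin, ubq11 and ss1, which on wild-type replicate 1 lay at -0.35 relative to replicate 2, and was lowest of its group on over-expression replicate 2 (1.74) too. After a further cyclic loess r was 0.210. That step was run on values already processed before deposition, so it cannot test the normalization done there. Less advanced fibre initiation on both arrays may account for part of the r of 0.217: the fibre list, which the published study makes a natural choice, lay at or below the 0.07 percentile of 10000 random lists of like intensity in both deviations, with medians of -0.45 and -0.38. Random lists hold unrelated probe sets, while its 12 come from 9 genes that may vary together. The percentiles can therefore overstate how unusual it is, and they do not test the explanation. Of the 12 fibre probe sets 10 are in other lists too, and the shared direction is not specific to the fibre list. MAP kinases had positive medians in both (0.20 and 0.47, percentiles 96.4 and 100, 6 probe sets higher and 5 lower each time), while ethylene genes went apart (percentiles 1.55 and 100) and cell wall genes had percentiles of 13.1 and 78.1.

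The rise from 5 to 238 calls between the transgenic lines without wild-type arrays goes with the spread of the wild-type pair. Its median variance, scaled for degrees of freedom, was 2.12 times that of the over-expression arrays and 4.05 times that of the silenced arrays (the scaling was added after the unscaled first ratio, 1.39, was seen). The log2 difference between the lines was the same in both fits, so the rise came from the error estimates, which no longer held the wild-type pair. The part of its wider spread was not separated from that of the changed degrees of freedom and prior. In the simulation with each group's own spread, this contrast gave 158.6 calls on average over all 7 arrays. The 2-group fit gave 155.4, so that simulation showed no such rise. Its calls over all 7 arrays were far from the 5 of the data, so it cannot decide on the role of the spread. No biological explanation was tested for this pattern.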

How the results depend on the processing

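The lists filled by symbol, the changes to replicate agreement and leaving out arrays for RNA quality were chosen after the data were seen; other alternatives were planned. For silenced against wild type, the count of 0 became 7 with a robust prior and ranged from 0 to 73 when each array was left out (73 without wild-type replicate 1, 35 without replicate 2). For over-expression against wild type, the count of 1 became 0 with the replicate block, the 2-group fit, cyclic loess, the brighter probe sets, array weights or an adjusted p of 0.01, and ranged from 0 to 475 over the left-out arrays (475 without wild-type replicate 2, 0 without any other). For over-expression against silenced, the count of 5 became 0 with the replicate block or an adjusted p of 0.01, 238 with the 2-group fit, 9 with median centring, 3 with the brighter probe sets (fewer tested) and 1209 with array weights, and ranged from 0 to 238 over the left-out arrays (238 without either wild-type array, 37 without over-expression replicate 2, 0 without any other). The trend, the further quantile step and the 2-fold floor kept these counts within 1.5 times. Lists past the threshold went from 1 to 0 with an estimated correlation, the replicate block, 1 probe set per gene or the lists as first written, to 4 with the brighter probe sets, to 2 with fry, and from 0 to 6 over the left-out arrays (0 without either wild-type array or over-expression replicate 3, 2 without silenced replicate 1, 3 and 6 without over-expression replicates 1 and 2). The covariance of both contrasts against wild type minus its simulated value was 0.0112, and 0.00225 to 0.0773 over the left-out arrays, highest without wild-type replicate 2, and 0.000196 over the brighter probe sets. These values used the pooled spread, which understates that of wild type and holds none of it when 1 wild-type array is left out. The difference turned to -0.0150 when each group had its own spread in the simulation, an alternative chosen after the results were seen, as the wild-type pair varies most. Mean replicate r was 0.989, and 0.962 over the brighter probe sets. The 3′ minus 5′ difference of over-expression against wild type (0.28) was 0.11 to 0.46. Except where stated, the cause was not tested.

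Replicate numbers do not pair the arrays: deviations of the wild-type and silenced pairs correlated at r = 0.0983, those of wild-type and over-expression replicates 1 and 2 at r = -0.270, and those of silenced and over-expression replicates 1 and 2 at r = 0.101. Of 161 named values, 0 changed sign under another normalization, the block or the 2-group fit, and 0 of the 92 among the brighter probe sets did. Without wild-type replicate 2 a few changed sign. Over the left-out arrays SEPALLATA3 ranged from -0.36 to 0.12 in the silenced line and from -0.42 to 0.0659 in over-expression. In over-expression Aux4 ranged from -0.00284 to 1.03 and CHS2 from -0.62 to 0.14. A lone array is assumed to vary like the other groups. Signals near the floor, such as GRPL1 and BTub1, are compressed. GhHD-1 itself has no value to vary.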

Other observations

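The test of group order was planned before its counts were seen; the genes named here were chosen after their values were seen.

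FLA4 and 3 probe sets of FLA19 were among 8 named probe sets whose arrays were fully ordered with wild type in the middle. At 1 of the FLA19 probe sets the silenced mean was 8.27 ± 0.14 (SD, n = 2), the wild-type mean 7.78 ± 0.18 (SD, n = 2) and the over-expression mean 7.31 ± 0.24 (SD, n = 3). WRKY15, the acid phosphatase-type gene PAP10 and GS ran the other way, lowest in silenced ovules.

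A few named probe sets differed widely between arrays of 1 group. The MAP kinase MPK3 had a probe set that read 10.84 and 7.96 in wild type, 7.49 and 7.76 in silenced and 7.38, 9.76 and 7.96 in over-expression ovules. The 10.84 and 9.76 were on wild-type replicate 1 and over-expression replicate 2, the arrays whose deviations are compared above. WRKY24 had an SD of 1.51 in wild type, 0.01 in the silenced line and 2.14 in over-expression. The ACC oxidase ACO1 had a probe set that read 11.84 on over-expression replicate 2 and 7.90 to 8.84 on the other arrays.

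A graded response to GhHD-1 level was predicted to place silenced and over-expression ovules on opposite sides of wild type more often than any other order. Of the probe sets whose groups did not overlap at all, 179 ran silenced, wild type, over-expression from low to high and 155 ran the reverse, where 114 each would be the share of chance. More had wild type at an end: 359 ran wild type, over-expression, silenced, 351 ran silenced, over-expression, wild type, and 237 ran wild type, silenced, over-expression; 91 ran over-expression, silenced, wild type. The predicted orders were thus not the most frequent, but the counts cannot decide on a graded response. The share of chance takes all arrays to vary alike, while the wild-type pair had 2.12 and 4.05 times the scaled variance of the other groups. A pair that wide falls less often between them, and wild-type replicate 2 lay close to the over-expression arrays.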
